A study of Mus musculus with 6 samples.

How the data were processed

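Bulk RNA-seq libraries were made from total RNA of mouse L4/5 dorsal root ganglia, 3 from mice given siNC and 3 from mice given siCLAP, with the NEBNext Ultra RNA kit, per the labels' protocols. This kit does not mark strand. FastQC 0.11.8, HISAT2 2.1.0, featureCounts 1.6.2 and the mm10 build are named in the submitters' processing notes. The gene annotation, the strand setting and the treatment of reads that match several genes are not given in the sources used here.

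The deposited file of each library lists 48401 gene symbols, in the same order in all 6, with a TPM value (abundance scaled to gene length and library total) and an expected count. The deposited expected counts need not be whole, as 66.5% were whole within 1e-06, and 400 tested genes had counts identical to those of another gene in all libraries. Gene families and gene copies may therefore have taken reads from each other. Groups and replicate numbers were taken from the sample titles.

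The plan fixed before the data were examined named limma on log2(TPM + 0.5), on the assumption that only TPM would be present, and a count test otherwise. Because the files hold counts, the main test was edgeR 4.0.16's quasi-likelihood test (R 4.3.3) on expected counts rounded to whole numbers, with TMM normalization, no covariate, and genes with a mean TPM of at least 1 over the 6 libraries (19141 genes). Genes passed at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Values per library are TMM-normalised CPM. The common biological coefficient of variation was 6.78%. With 3 libraries against 3 an exact permutation test of a single gene cannot give a p below 0.1, so single genes were tested only in the models across all genes.

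Gene lists for cell types, pathways and stress responses of the ganglion, 38 in number with 593 entries, were fixed at the same stage, and a ribosomal protein list was taken by symbol, which also admits ribosomal protein S6 kinases and paralogs such as Rpl22l1. The 33 lists with at least 5 measured members were tested with camera in limma 3.58.1 at a preset correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 33 lists. Camera with an estimated correlation passed 0 lists after adjustment and 5 at an unadjusted p under 0.05, fry passed 3 (glucocorticoid, non-peptidergic nociceptor and pruriceptor), and camera on ranks passed 10. Lists of caudal Hox and leptomeningeal genes were added after seeing the data.

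Named genes followed a rule fixed in advance. It took the 12 largest rises and 12 largest falls among genes that passed, with groups that did not overlap and a mean TPM of at least 2 in the higher group, with at most 3 predicted genes per direction. It also took up to 4 members of each list with the smallest p, and 11 itch and pain genes. Of the list members only part is named in the text. Hoxd10, Hoxd11, Ptgds, Slc47a1, Hoxa10, Hoxc10, Hoxc11, Tmem79, Nr1d1, Nr1d2, Cysltr2 and the genes below the TPM filter were chosen after their values were seen.

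The scripts were tested on counts simulated for the 19141 genes from the observed means, library sizes and dispersions. The changed genes were drawn only from those with a mean above 2 CPM. Of 50 such genes each changed by 1.25, 1.5, 2 and 3-fold, 40%, 74%, 96% and 100% were recovered in the right direction. Recovery of single genes below that level was not tested. Of 18926 unchanged genes 12 were called, among 171 calls. A list of 15 genes shifted by −0.3 was called, as was 1 of the 32 other lists. Each gene was simulated independently of the others. The simulation therefore gives no false-call rate for real lists, whose members vary together.

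Libraries of one group differed from each other by more than counting noise, with a mean chi-square per gene of 4.30 to 10.0 over 18309 genes, so none was a repeat deposit. Mitochondrial transcripts made up 1.28% to 1.64% of counts and TMM factors were 0.995 to 1.011. A floor of 3 counts corresponds to 0.0648 CPM in the deepest library and 0.140 CPM in the shallowest. Floors cover counting error only. Intervals of list differences are 95% intervals from the spread between libraries, those of fitted gene changes are 2 standard errors, and those of count ratios cover counting error only.

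Limma on log2(TPM + 0.5), the test the plan named, was kept as an alternative. Other alternatives covered the pseudocount, the TPM filter, scaling, variance model, library weights, the replicate number as a block, and each library left out. Those chosen after seeing the data were DESeq2 1.42.0, limma voom, edgeR with robust settings, the 2 libraries with high interferon genes left out, covariates for Hox and leptomeningeal levels, and removal of trends with gene length or GC content. Gene coordinates, biotypes, exon overlaps and GC content came from GENCODE M21 on the same build, which holds 37421 of the symbols and 16308 of those tested. Gene length was the ratio of count to TPM, relative to the median gene.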

Results

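RNA sequencing was carried out on L4/5 dorsal root ganglia (DRG), the clusters of sensory neuron cell bodies beside the spinal cord, from male C57BL/6J mice aged 8 weeks. The mice had received small interfering RNA by intrathecal injection, into the fluid around the spinal cord. The siRNA was either siNC, taken here as the control, or siCLAP, directed at the long intergenic noncoding RNA (lincRNA) CLAP. Each group held 3 libraries. Total expected counts were 35702727, 46317735 and 21386768 in siNC-1, siNC-2 and siNC-3, and 39239131, 25982046 and 29583942 in siCLAP-1, siCLAP-2 and siCLAP-3. Between 26004 and 27505 genes had a count above 0 in a library. The labels do not say whether the libraries came from separate mice, so p-values measure only the spread between these libraries.

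The comparison of siCLAP with siNC asked which DRG transcripts differ after knockdown of CLAP, a lincRNA that the study's title links to itch sensation. The level of CLAP itself was not analysed here, because no gene row carries that name, so the knockdown was not checked. Of 337 annotated lincRNAs that were tested, 0 changed in edgeR's quasi-likelihood test, 36 had an unadjusted p under 0.05 (16 of them lower in siCLAP), and DESeq2 called 3. Over all 19141 tested genes 56 changed and 3248 had an unadjusted p under 0.05 in edgeR's test, and DESeq2 called 608. At that share of changed genes, 0 of 337 does not set lincRNAs apart. Tested symbols absent from the annotation are not in the lincRNA count.

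Sst, which encodes somatostatin, a neuropeptide of itch-related sensory neurons, fell 3.19-fold in siCLAP, from 3.43 ± 0.632 to 1.08 ± 0.158 normalised CPM (counts scaled to library size; mean ± SD, n = 3 libraries per group; log2 fold change −1.67 ± 0.19 SE, adjusted p = 0.0141). Several genes of non-peptidergic nociceptors and pruriceptors, the small-diameter neurons that respond to painful and itch-producing stimuli, fell by smaller amounts. Mrgprd, a receptor of non-peptidergic nociceptors, fell from a mean of 256 to 198 CPM (log2 fold change −0.37 ± 0.06, adjusted p = 0.0397). Scn11a and Scn10a, which encode the nociceptor sodium channels Nav1.9 and Nav1.8, fell by 0.43 ± 0.05 and 0.35 ± 0.06 on the log2 scale. Plcb3, a phospholipase C that acts downstream of histamine and other itch receptors, fell by 0.43 ± 0.04 on the log2 scale (adjusted p = 0.00621).

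In the list of 14 non-peptidergic nociceptor genes, 4 fell, 0 rose and 10 did not pass, and all 14 estimates were negative (median log2 fold change −0.22). The 4 were Scn11a, Plxnc1, Mrgprd and Gfra2, with Plxnc1 lower by 1.23-fold and Gfra2, the co-receptor for neurturin, lower by 1.22-fold. Adjusted over the list alone, 11 members passed. In the pruriceptor list, 5 of 24 measured members fell (Plcb3, Sst, Scn11a, Plxnc1 and Mrgprd) and 19 did not pass, with a median of −0.27. Adjusted over the list alone, 13 members were lower and 2 higher. Both lists moved down in the camera test (adjusted p = 3.68e-18 and 1.60e-14), a call that was lost with an estimated correlation (adjusted p = 0.119 for each). The lists share Scn11a, Plxnc1, Mrgprd and Lpar3, so their results are not independent of each other.

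Other itch and pain genes fixed by name did not pass. Mrgpra3, a chloroquine receptor of pruriceptors, stood at −0.23 ± 0.10 (adjusted p = 0.275), and Osmr, a subunit of the interleukin-31 receptor, at −0.26 ± 0.05 (adjusted p = 0.0524). Nppb, a natriuretic peptide of itch neurons, Il31ra, the other interleukin-31 receptor subunit, and Hrh1, a histamine receptor, stood at −0.14 ± 0.18, −0.10 ± 0.10 and −0.06 ± 0.19. Signs turned for Nppb with a covariate for Hox level (0.12), and for Il31ra and Hrh1 without siNC-3 and siCLAP-2 (0.09 and 0.07). The irritant-sensing channels Trpv1 and Trpa1 were at −0.07 ± 0.06 and −0.10 ± 0.05. The peptidergic nociceptor genes Calca and Tac1 were at 0.07 ± 0.05 and 0.34 ± 0.07 (adjusted p = 0.530 and 0.0766), the sign of Calca turning with 2 corrections chosen after seeing the data. In the peptidergic nociceptor list 0 of 13 genes passed edgeR's test, 3 were higher and 1 lower when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.122).

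**Figure D1:**
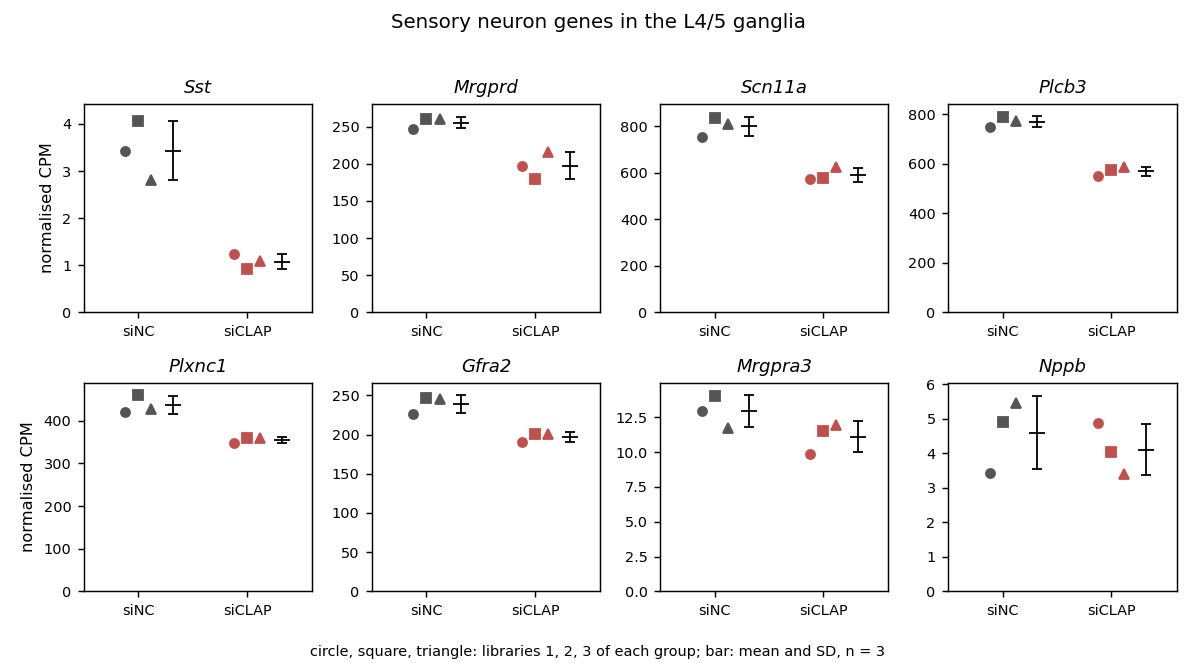
Normalised CPM of 8 sensory neuron genes in each library (y axis, linear from 0) for siNC and siCLAP (x axis), with the mean and SD beside the 3 libraries of each group. The siCLAP libraries lie below all siNC libraries for Sst, Mrgprd, Scn11a, Plcb3, Plxnc1 and Gfra2, while the groups overlap for Mrgpra3 and Nppb.

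Among glucocorticoid-induced genes, 6 fell in siCLAP and 0 rose. Zbtb16, a transcription factor induced by glucocorticoids, fell 2.65-fold, from 16.5 ± 3.82 to 6.21 ± 1.28 CPM (log2 fold change −1.41 ± 0.18, adjusted p = 0.0215, n = 3 per group). Sgk1, the serum and glucocorticoid regulated kinase, fell by 0.58 ± 0.08 on the log2 scale, the clock gene Per1 by 0.54 ± 0.07 and the transcription factor Klf9 by 0.29 ± 0.05. Of 16 measured list members 10 did not pass (median −0.47), and 11 were lower when adjusted over the list alone. Camera placed the list lower (adjusted p = 7.49e-19), and the adjusted p was 0.119 with an estimated correlation. Klf15, another glucocorticoid-induced transcription factor outside the list, fell from 11.8 ± 1.02 to 6.99 ± 0.944 CPM (log2 fold change −0.76 ± 0.11).

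Antigen presentation genes of MHC class II were lower as a list (median −0.86 over 7 members, camera adjusted p = 4.91e-09; adjusted p = 0.121 with an estimated correlation). H2-Eb1 fell by 0.88 ± 0.15 on the log2 scale (adjusted p = 0.0409). The remaining 6 members did not pass, among them H2-Aa at −1.15 ± 0.22 (adjusted p = 0.0565) and H2-Ab1 at −0.86 ± 0.19, and 5 were lower when adjusted over the list alone. In the myelinating Schwann cell list, Egr2, the transcription factor that drives peripheral myelination, fell by 0.76 ± 0.13 on the log2 scale, and 17 of 18 members did not pass, with 5 lower when adjusted over the list alone. Mal and Fa2h, 2 further myelin genes, stood at −0.23 ± 0.05 and −0.36 ± 0.10. The list median was −0.18 (camera adjusted p = 7.42e-07; adjusted p = 0.419 with an estimated correlation), and it was 0.0303 with a covariate for leptomeningeal level, −0.0678 without siNC-1 and −0.309 without siNC-2. The mean log2 level of the list was 6.30, 5.88 and 6.14 in siNC-1, siNC-2 and siNC-3, against 5.91, 5.90 and 5.87 in the siCLAP libraries. In the heat shock and ER stress list 1 of 16 members changed. This was Hspa1b, an inducible Hsp70, which fell by 1.14 ± 0.17 on the log2 scale, and 1 member was higher and 2 lower when adjusted over the list alone. The list median was −0.10 (camera adjusted p = 0.0256; adjusted p = 0.419 with an estimated correlation), a call that ended in 19 of 31 alternatives, among them without siNC-3 (adjusted p = 0.108) or siCLAP-3 (0.0698).

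The siCLAP libraries were higher in Atf3, a transcription factor induced in injured sensory neurons, which rose 1.95-fold, from 8.93 ± 1.69 to 17.2 ± 3.38 CPM (log2 fold change 0.97 ± 0.16, adjusted p = 0.0409). The remaining 20 of 21 members of the nerve injury and regeneration list did not pass, among them Gadd45a at 0.38 ± 0.09 and Adcyap1 at 0.34 ± 0.08, and 8 were higher when adjusted over the list alone. The list median was 0.26 (camera adjusted p = 3.68e-09; adjusted p = 0.121 with an estimated correlation). Pvalb, a marker of proprioceptors, rose by 0.45 ± 0.06 on the log2 scale, as the 1 member of 18 that passed in the myelinated mechanoreceptor and proprioceptor list. Ldhb and Whrn stood at 0.17 ± 0.04 and 0.24 ± 0.07, and 5 members were higher when adjusted over the list alone. The list median was 0.12 (camera adjusted p = 0.000326; adjusted p = 0.410 with an estimated correlation), and it was −0.0298 with a covariate for Hox level. Ednrb, an endothelin receptor of satellite glia, rose from 92.9 ± 3.04 to 127 ± 13.4 CPM, and 13 of 14 satellite glia genes did not pass, Fabp7 standing at 0.38 ± 0.07, with 2 higher when adjusted over the list alone. The list median was 0.12 (camera adjusted p = 0.00607; adjusted p = 0.348 with an estimated correlation), and the call ended in 14 of 31 alternatives, among them without siNC-2 (median 0.0602, adjusted p = 0.0982), while the median was 0.0567 without siCLAP-1.

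Genes of nuclear oxidative phosphorylation, ribosomal proteins and pan-neuronal function were higher as lists in the camera test, with 0 single genes past edgeR's test in each. Medians were 0.16 over 23 genes (camera adjusted p = 1.39e-08), 0.10 over 93 genes (3.92e-08) and 0.07 over 16 genes (0.0403), and the calls were lost with an estimated correlation (adjusted p = 0.410, 0.628 and 0.516). Cox5a and Ndufc1, of respiratory complexes IV and I, stood at 0.33 ± 0.08 and 0.36 ± 0.09, and the ribosomal protein gene Rpl29 at 0.18 ± 0.05. Adjusted over the list alone, 8 oxidative phosphorylation genes were higher, 0 ribosomal protein genes passed, and 3 pan-neuronal genes were higher and 2 lower, such as Stmn3 at 0.22 ± 0.06 and Syt1 at −0.19 ± 0.05. The pan-neuronal call ended in 19 of 31 alternatives, among them without siNC-3, siCLAP-1 or siCLAP-3 (adjusted p = 0.156, 0.113 and 0.0645). The ribosomal protein median was 0.0564 without siCLAP-2 and 0.165 without siCLAP-3, whose mean log2 list level of 5.40 lay below those of siNC-2 (5.42) and siNC-3 (5.46). Fold changes of protein-coding genes also followed gene length, from a median of 0.08 in the 2687 shortest to −0.04 in the 2687 longest. Not all libraries of a group shared this trend, as medians relative to the mean of all libraries ran from −0.0798 to 0.0474 in siNC-1 and from 0.0798 to −0.0456 in siCLAP-2, but from −0.000834 to −0.00878 in siNC-2 and from −0.00894 to 0.00299 in siCLAP-3.

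**Figure D2:**
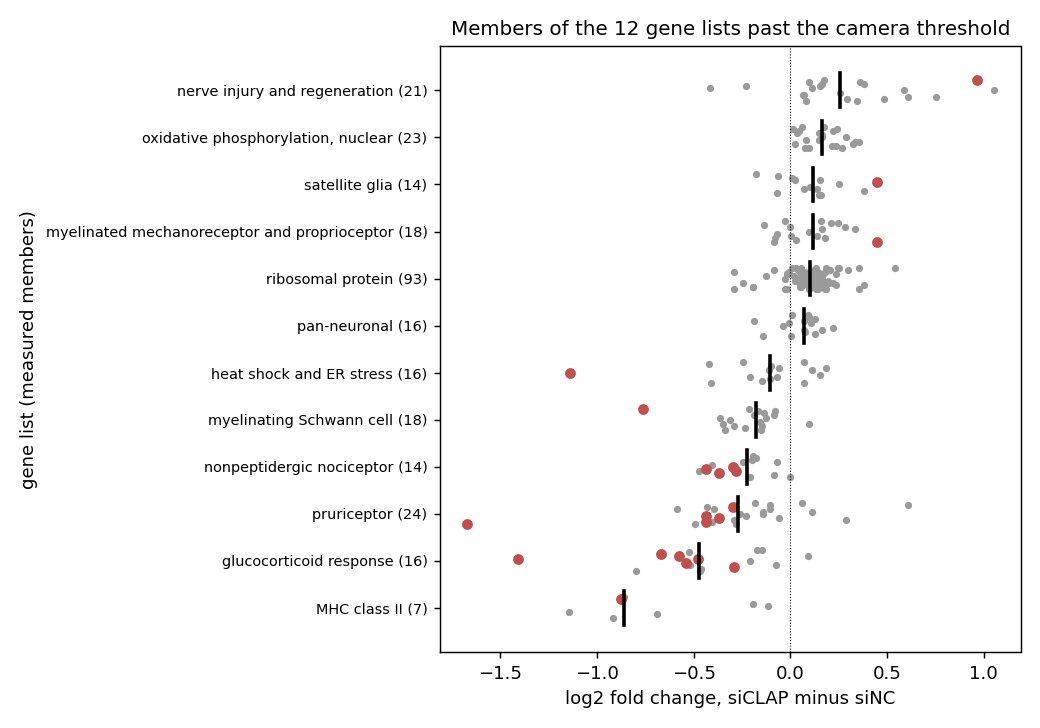
Log2 fold change of siCLAP minus siNC (x axis) for each measured member of the 12 gene lists that passed camera (y axis, number of members in brackets). Red points passed edgeR's test over all genes, grey points did not, and black bars mark list medians, which run from −0.86 for MHC class II to 0.26 for nerve injury and regeneration.

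The remaining 21 tested lists did not pass (camera adjusted p from 0.0657 to 0.949). In the nociceptor ion channel list Scn11a and Scn10a fell while 21 of 23 members did not pass, such as P2rx3 at −0.18 ± 0.04 and Asic1 at 0.25 ± 0.07. In the immediate early list Atf3 rose and 13 of 14 members did not pass, Dusp1 standing at 0.34 ± 0.07. The C-fibre touch and cold neuron, fibroblast, endothelial, mural, macrophage, mast cell, erythroid, non-myelinating Schwann cell, RNA interference, acute inflammation, complement, cell cycle, cholesterol synthesis, histone and well-known long noncoding RNA lists held no gene that passed edgeR's test over all genes. In the C-fibre list 3 of 11 members were lower and 0 higher when adjusted over the list alone, among them Th at −0.30 ± 0.06. Of its 11 estimates 7 were negative and 4 positive. Mitochondrially encoded genes had a median of −0.02 but a mean of 0.41 over 13 genes, and camera placed them lower without passing (adjusted p = 0.914). The mean rests largely on siCLAP-1, where mt-Atp8 and mt-Atp6 stood at 30.1 and 32.2 CPM, against at most 1.56 and 6.63 CPM in the other 5 libraries, and their estimates turned negative without it (−0.16 and −0.46). These 2 genes overlap on the same strand, so their values may come partly from the same reads. Lists for T and NK cells, B and plasma cells, neutrophils, skeletal muscle, central glia, and fat, cartilage and bone had 1 to 4 measured genes, too few to test. The type I interferon list had a median of 0.01 and a mean of −0.02 over 20 genes. Its mean log2 level was 5.24 in siNC-3 and 5.20 in siCLAP-2, against 4.40 to 4.57 in the other 4 libraries.

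Over all 19141 genes tested, 56 changed, of which 14 rose and 42 fell. At an unadjusted p under 0.05 the split was nearly even, with 1574 genes higher and 1674 lower. Folds were small, with a median of 1.36, a largest of 3.19 (Sst) and only 5 genes above 2-fold. The largest falls after Sst were in Etnppl, Zbtb16, Slc9a3, Hspa1b, H2-Eb1, Sec14l5, Lctl, Chrna3, Egr2, Klf15 and Shisa6, from −1.42 ± 0.25 for Etnppl, an ethanolamine phosphate lyase, to −0.73 ± 0.12 for Shisa6. Chrna3, a nicotinic receptor subunit, fell by 0.78 ± 0.13, and Slc9a3, a sodium-proton exchanger, by 1.23 ± 0.18. The largest rises after Atf3 were in Gabrg1, a GABA-A receptor subunit (0.57 ± 0.10), Shox2 (0.47 ± 0.08), Ednrb, Pvalb, Serpina3n (0.45 ± 0.06), Fam19a2, Shf, Nsg1, the neuropeptide Y receptor Npy1r (0.37 ± 0.06), S100a11 and Gm13889 (0.35 ± 0.06). All 56 had groups that did not overlap, as did 21.5% of all tested genes. The mean over all splits into 3 and 3 is 10%. Genes vary together across the libraries, so a single split can stray far from that mean without a group difference.

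The number of changed genes depended on single libraries, at 38 without siNC-1, 0 without siCLAP-1 (1960 genes at an unadjusted p under 0.05), 4 without siNC-3, 157 without siNC-2 and 340 without siCLAP-3, and on the test, at 0 with limma on log2(TPM + 0.5) (3028 unadjusted) and 608 with DESeq2 (239 higher and 369 lower). Other splits of the 6 libraries into 3 and 3 called 0 genes each but up to 15 gene lists, against 12 for the real groups. At an unadjusted p under 0.05, the split of siNC-1, siNC-3 and siCLAP-3 from the rest gave 2204 genes. The real groups gave 3248. Each other split mixes both groups, so a group difference would widen its spread and lower its calls. The list count was 19 without siCLAP-2.

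Hoxd10 and Hoxd11, which mark position along the spine, and leptomeningeal genes, from the thin membranes around the spinal cord and nerve roots, had lower values in siCLAP, as did the non-peptidergic nociceptor, pruriceptor, glucocorticoid, MHC class II, myelinating Schwann cell and heat shock lists above. These genes were chosen after seeing the data. On the level of the whole leptomeningeal list the groups overlapped, with mean log2 levels of 2.27 and 2.93 in siNC-1 and siNC-3, 1.01, 0.54 and 0.29 in the siCLAP libraries, and a level just below that of siCLAP-1 in siNC-2. Medians were −1.52 over 5 caudal Hox genes (camera unadjusted p = 0.0121, and p = 0.203 with an estimated correlation) and −1.57 over 9 leptomeningeal genes (9.79e-09 and 0.0837). Both depended on single libraries, as the caudal Hox median was −3.29 without siCLAP-2 and −0.883 without siCLAP-1, and the leptomeningeal median −0.955 without siNC-3. The unadjusted camera p of the caudal Hox list was 0.0956 without siNC-2 and 0.0605 without siCLAP-3. The caudal Hox genes did not all move together. Hoxa10, the most abundant, stood at 0.14 ± 0.06 (32.4 against 35.8 CPM) and Hoxc10 at −0.13 ± 0.11. Hoxc11, whose value is the median, was at −1.52 ± 0.80 with means of 1.59 and 0.660 CPM. Like Hoxd10 and Hoxd11, Hoxc11 was lowest in siCLAP-1 and siCLAP-3 (0.077 and 0.034 CPM) and higher in siCLAP-2 (1.87 CPM). Hoxd10, a homeobox gene that marks caudal spinal levels, was at 8.61, 16.0 and 14.9 CPM in the siNC libraries and 1.82, 8.08 and 0.748 CPM in the siCLAP libraries (log2 fold change −1.96 ± 0.55, adjusted p = 0.117). Hoxd11 was 5.01-fold lower (adjusted p = 0.0856), at 6.897, 13.562 and 12.181 CPM against 1.076, 5.338 and 0.476 CPM. Without siCLAP-2, Hoxd10, Hoxd11 and Hoxc11 stood at −3.29, −3.74 and −4.78 and passed (adjusted p = 0.00712, 0.00712 and 0.0255). Ptgds, a prostaglandin D synthase abundant in leptomeninges, was at 30.7, 6.72 and 31.4 CPM against 4.71, 2.29 and 1.26 CPM (adjusted p = 0.0560), and Slc47a1 was at −1.78 ± 0.38. With the Hoxd10 and Hoxd11 level as a covariate 442 genes changed (187 higher and 255 lower), 24 of them among the 56, and with the leptomeninges level 12 genes changed (8 higher and 4 lower), 5 of them among the 56.

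**Figure D3:**
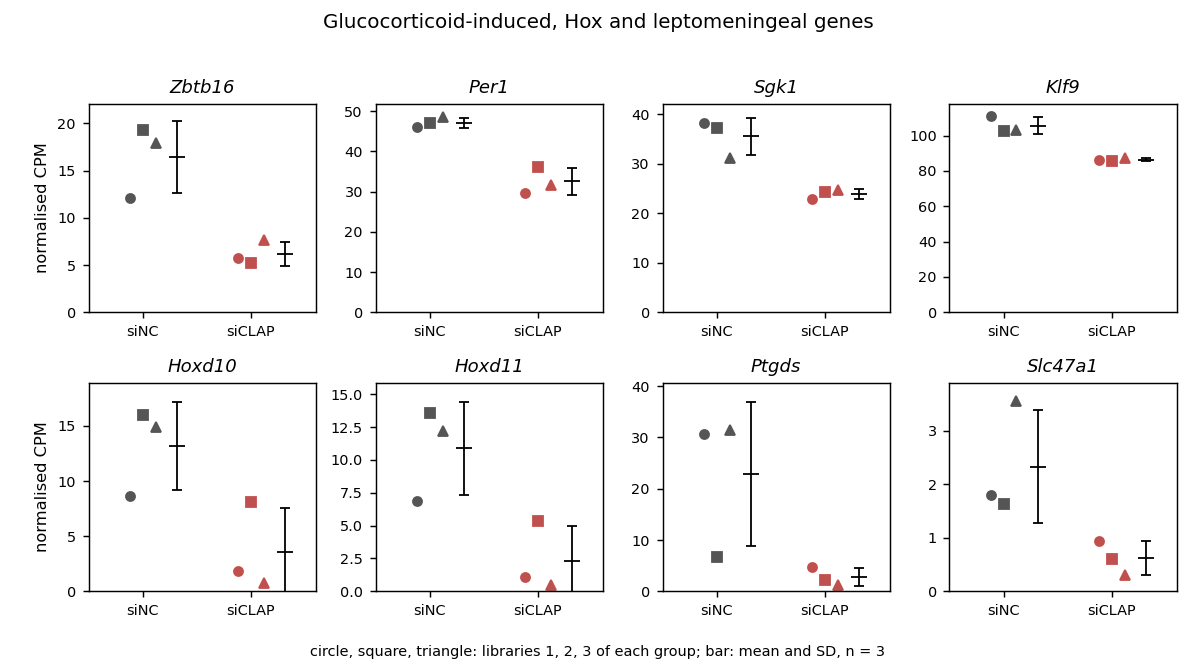
Normalised CPM (y axis, linear from 0) of the glucocorticoid-induced genes Zbtb16, Per1, Sgk1 and Klf9, the Hox genes Hoxd10 and Hoxd11 and the leptomeningeal genes Ptgds and Slc47a1 in each siNC and siCLAP library (x axis), with the mean and SD of the 3 libraries of each group. The 3 siCLAP libraries lie below the siNC libraries in each panel, and Ptgds is high in siNC-1 and siNC-3 (30.7 and 31.4) but not in siNC-2 (6.72).

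In the mm10 mouse genome, Sst (ENSMUSG00000004366.4) lies on chromosome 16 from 23889573 to 23890958 on the minus strand, and Mrgprd (ENSMUSG00000051207.7) on chromosome 7 from 145314835 to 145324086 on the plus strand. Scn11a (ENSMUSG00000034115.10) spans chromosome 9 from 119753759 to 119825456, and Scn10a (ENSMUSG00000034533.10) the same chromosome from 119608456 to 119719322. Plcb3 (ENSMUSG00000024960.9) spans chromosome 19 from 6952325 to 6976470, and Zbtb16 (ENSMUSG00000066687.5) chromosome 9 from 48654297 to 48836222. Atf3 (ENSMUSG00000026628.13) spans chromosome 1 from 191170296 to 191218039. All are annotated as protein-coding, and values are given per gene, not per transcript or exon. Exons of Plcb3, Shox2, Nsg1 and Lctl overlap those of Ppp1r14b, Rsrc1, Stx18 and Zwilch on the opposite strand, and exons of Gm13889, Plxnc1 and Il31ra overlap a predicted gene on the same strand. Overlaps were listed only for genes that the naming rule took, not for those chosen after their values were seen, such as Nr1d1. Among other genes of that rule given above or below, exons of P2rx3, Gadd45a, Dusp1, Dbp, Cox5a and Ago2 also overlap a gene on the opposite strand. The library kit does not mark strand, so reads in those overlaps cannot be assigned with certainty. Hspa1b, Serpina3n and Mrgpra3 have close paralogs, and their values carry the same uncertainty.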

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

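Genes below the TPM filter entered no comparison above, and of 11206 such genes 30 passed when edgeR was run with no filter, 7 of them higher and 23 lower in siCLAP than in siNC (466 at an unadjusted p under 0.05). All of these values were found after the main result was seen. The higher genes, flagged as signal above the control in genes outside the main test, were Abra (log2 fold change 4.638), Mobp (2.739), Il22ra2 (2.177), Pdzrn4 (1.211), Adra1a (1.062), Glyat (0.8046) and Lmx1b (0.793). The lower genes ran from −5.494 (Gm11585, 17 counts in siNC and 0 in siCLAP) to −0.7239 (Hpcal4, 203 and 111 counts). None of the 30 passed when genes with a mean TPM of at least 0.1 were tested, where adjusted p ran from 0.0617 to 0.135 for the higher genes and from 0.0513 to 0.265 for the lower.

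Abra had 1 count over the siNC libraries and 33 over the siCLAP libraries, a ratio per total count of 36 with a 95% counting interval of 6.03 to 1460, and 21 of the 33 came from siCLAP-1. Mobp, a myelin gene of central glia, had 7 and 47 counts, of which siCLAP-1 gave 36. Il22ra2 had 7 and 31 counts, of which siCLAP-1 gave 15. Fitted fold changes at such counts depend on the prior count, and intervals cover counting error only. Pdzrn4, Adra1a, Glyat and Lmx1b had 41, 51, 88 and 95 counts in siNC and 89, 101, 143 and 152 in siCLAP, of which siCLAP-1 gave 39, 55, 58 and 64.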

How the results depend on the processing

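Alternatives named in processing as chosen after seeing the data are marked here as added. The count of 56 changed genes stayed within 1.5 times with median-of-ratios scaling, without mitochondrial, ribosomal RNA and hemoglobin genes, and with the added voom, gene length and GC settings. It rose to 135 with a TPM minimum of 0.1, 118 with 5, 835 with no filter and 107 with protein-coding genes alone, and to 608 with DESeq2, which gave no adjusted p for 5570 genes, 133 with robust edgeR and 442 with the Hox covariate (all 3 added). It fell to 12 with the leptomeninges covariate and 13 without siNC-3 and siCLAP-2 (both added). Limma on TPM gave 0 with each pseudocount (0.1, 1, 2 and 0.5, the test first planned), with quantile normalization, without trend and with robust settings, and 2 with library weights, with 2674 to 4604 genes at an unadjusted p under 0.05. At an adjusted p under 0.10, 535 genes passed, 3248 at an unadjusted p under 0.05, and 17 at 1.5-fold or more. Leaving out 1 library gave 0 (without siCLAP-1) to 340 (without siCLAP-3), with 4 without siNC-3 and 157 without siNC-2. The causes were not tested. All of the 56 that were tested kept their direction, at an unadjusted p under 0.05, in every alternative. The 56 were selected on the same libraries that every alternative reuses, so this was largely fixed by that choice.

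The 12 gene lists became 0 with an estimated correlation and 3 with fry, and 12 to 19 with 1 library left out, 19 without siCLAP-2. Of 31 alternatives, the pan-neuronal and heat shock calls were lost in 19 each and the satellite glia call in 14, against at most 3 for each of the other lists, sign turns aside. The pan-neuronal call was lost without siNC-3, siCLAP-1 or siCLAP-3 (adjusted p = 0.156, 0.113 and 0.0645), the satellite glia call without siNC-2 (0.0982), and the heat shock call without siNC-3 or siCLAP-3 (0.108 and 0.0698). The myelinated mechanoreceptor and proprioceptor list turned to a median of −0.0298 with the Hox covariate, and the myelinating Schwann cell list to 0.0303 with the leptomeninges covariate. Among 86 genes chosen by the naming rule or after seeing the data, 1859 of 2482 values kept direction and side of the threshold, 455 lost their call, 141 gained one and 27 turned sign. With the causes untested, the Hox covariate turned Nppb (0.12), Calca (−0.0624), Tmem79 (0.16), Hoxc10 (0.19), Hoxc11 (0.94) and Hoxd10 (0.16), from which it was built. The leptomeninges covariate turned Il31ra (0.0262), Hrh1 (0.00916) and Nr1d1 (−0.0920), and leaving out siNC-3 and siCLAP-2 turned Il31ra (0.0879), Hrh1 (0.0685) and Nr1d1 (−0.0578). Other turns were Calca (−0.0154, length), Tmem79 (0.00478 at a TPM minimum of 0.1, 0.00963 with GC) and Nr1d1 (−0.0105, library weights). With 1 library left out, Il31ra ran from −0.2065 to 0.00081, Hrh1 from −0.318 to 0.0909, Tmem79 from −0.0541 to 0.0633, Nr1d1 from −0.0291 to 0.0731, mt-Atp8 from −0.16 (without siCLAP-1) to 4.03 and mt-Atp6 from −0.46 (without siCLAP-1) to 2.32. Medians moved by over 1.5 times for the myelinating Schwann cell list (−0.0678 without siNC-1, −0.309 without siNC-2), the ribosomal protein list (0.0564 without siCLAP-2, 0.165 without siCLAP-3) and the satellite glia list (0.0602 without siNC-2, 0.0567 without siCLAP-1). Adjusted p over all alternatives ran up to 0.119 for the glucocorticoid, non-peptidergic and pruriceptor lists, 0.121 for MHC class II and nerve injury, and 0.348 to 0.937 for the rest.

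Same-numbered libraries of the 2 groups deviated from their group means with correlations of 0.0656, 0.00766 and −0.0443, so the numbers were not taken as pairs. With the replicate block 203 genes changed, 54 of them among the 56, the list count was 12, and Tmem79 turned to 0.00301. Depth limits genes near 1 CPM, as Sst was in siCLAP (mean 1.08 CPM, against 3.43 CPM in siNC).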

Other observations

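Tests of neuron loss, time of day and the gene length trend of the oxidative phosphorylation and ribosomal protein lists were chosen after the results were seen, and the length correction and both covariates themselves after seeing the data. The length criterion was first set for those lists jointly, decided nothing in that form, and was split by list, and later joined with a bound on the spread between libraries, after the values were seen. The criterion for fewer non-peptidergic neurons was also rewritten after its values were seen, and was undecided in both forms. Patterns were found and tested on the same 6 libraries, so each reading below is a hypothesis.

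Clock genes of the ganglion gave values in both directions. Per1 fell by 0.54 ± 0.07 on the log2 scale, while Per2 stood at −0.55 ± 0.13 (adjusted p = 0.0800), Dbp at 0.39 ± 0.13 (adjusted p = 0.165) and Nr1d2 at 0.08 ± 0.05. The circadian list of 15 genes held 1 lower gene and did not pass (camera adjusted p = 0.137). Among stromal genes, the fibroblast and matrix list had values in both directions with 0 genes past edgeR's test (1 higher and 1 lower when adjusted over the list alone), Mfap5 at −0.51 ± 0.10 (adjusted p = 0.0584) and Lum at 0.67 ± 0.15 (adjusted p = 0.0795). Of the RNA interference genes, Ago2 was nearest to the threshold (−0.17 ± 0.05, adjusted p = 0.101).

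The non-peptidergic nociceptor and pruriceptor genes were lower in siCLAP by a mean of 0.24 on the log2 scale over 34 genes (difference −0.24, 95% interval −0.33 to −0.15). With the Hoxd10 and Hoxd11 level as covariate the difference was −0.24 (interval −0.43 to −0.05), so that level did not account for it. This does not decide on ganglia from another spinal level. Hoxd10 and Hoxd11 were chosen from these data, and their mean log2 level did not overlap between groups (siNC-1 lowest at 2.96, siCLAP-2 highest at 2.73). Hoxa10 (0.14) and Hoxc10 (−0.13) did not move with them, while Hoxc11 (−1.52) was lowest in the same siCLAP libraries. The gene length trend was argued against as the whole cause. Its removal left a median of −0.23 (−0.22 before), a mean difference of −0.254 (interval −0.335 to −0.172) and 5 of 6 calls. For Sst, 5 markers of its neuron class, Nppb, Il31ra and Osmr among them, were less low than Sst. The closest was Cysltr2, with a difference of 1.09, or 4.72 combined standard errors. An equal loss showing in all 5 markers was thus argued against. Sst had the largest fall of the genes that passed, however, so smaller falls elsewhere were partly fixed by that choice. Fewer neurons of that class were not excluded, because markers that other cells also express would be less low. For Mrgprd and its list, an equal loss showing in all members was argued against, since the 14 values differed beyond their errors (heterogeneity 62.8 on 13 degrees of freedom, weighted mean −0.235) and Tmem79 stood at −0.00134 (interval −0.13 to 0.13), but fewer non-peptidergic neurons stay open, because members that other cells also express would be less low. An effect of siCLAP on these transcripts was not tested apart from the groups, and the knockdown was not checked.

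The glucocorticoid-induced genes had a mean difference of −0.44 over 16 members (95% interval −0.68 to −0.20). With the leptomeninges level as covariate the difference was −0.54 (interval −0.97 to −0.10), so that level did not account for it. This does not decide on less meningeal tissue. The 9 leptomeningeal genes were chosen from these data, and some were near 1 CPM, such as Crabp2 (means of 1.09 and 0.906 CPM in siNC and siCLAP). Their level measures tissue only roughly, so a difference can remain after it. Collection at another time of day cannot be told apart from the groups, because the labels give no collection times. Nr1d1, a gene of strong daily rhythm, stood at 0.0200 (interval −0.10 to 0.14), which does not decide, as Nr1d1 and Arntl can be at trough and peak at the same time. Lower stress or hormone levels at collection could also lower these genes and were not tested.

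The higher oxidative phosphorylation and ribosomal protein genes are short, with median lengths of 0.448 and 0.358 of the median gene. Removing the length trend of each library moved the oxidative phosphorylation median from 0.16 to 0.0863 and kept the camera call at the preset correlation (adjusted p = 0.000158; adjusted p = 0.451 with an estimated correlation). The mean difference between libraries was then 0.0953 (95% interval −0.00928 to 0.200), which includes 0, so whether the trend may account for all of it stays open. For the ribosomal protein list the median moved from 0.10 to 0.0341 and the call ended (adjusted p = 0.0536; mean difference 0.0259, interval −0.0878 to 0.140), which is consistent with a length-dependent difference between libraries. No biological explanation was tested for either list.

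The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real groups gave 56 changed genes and the highest other split 0, so 1 split of 10 gave as many. Because each other split mixes both groups, a group difference would lower its calls, so the contrast of 56 with 0 does not measure chance. For gene lists the real groups gave 12 and the highest other split 15, and 6 of the 10 splits gave at least 12.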
